A study of Homo sapiens with 11 samples.

How the data were processed

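Whole endometrium from women treated with clomiphene citrate was profiled by RNA sequencing, per the labels, with 6 libraries from linings called optimal and 5 from linings called suboptimal. Total RNA was extracted with TRIzol and an RNeasy kit, per the labels' protocols. The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the total of mapped fragments), with 1 value per gene symbol and library; the unit is taken from the name of the deposited table and from the tools named in the submitters' processing notes. Those notes name TopHat2 2.0.4, Cufflinks 2.0.2 and the hg19 build, with no role or order. The annotation, filters, scaling between libraries and use of strand are not given in the sources used here. The estrogen receptor ChIP-seq that the series describes was not analysed here. The reference used here is on GRCh38 while the notes name hg19, so no coordinates are printed. It served only to list the genes of the Y chromosome and to give transcript lengths and GC content by symbol.

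The table held 27978 gene symbols, 0 of them repeated, and 2699 were at 0 in every library. Genes of the Y chromosome, XIST and TSIX (115 symbols) were removed before any test, which left 27863. FPKM keeps no read counts, and the low values were examined for the step that 1 read is worth. Ratios of low values at 1781 genes seen in 2 to 5 libraries gave an estimate of the relative depth of the libraries. Of 55 library pairs, 52 lay within 0.05 (log2) of a common scale. By this estimate the deepest library had 1.71 times the depth of the shallowest. It measures depth only if no scaling between libraries beyond the mapped total was applied, which is not known. The absolute depth is unknown, so no counting interval or detection floor was computed and no count model was used. The group means of relative depth were 0.967 ± 0.108 (optimal, n = 6) and 1.02 ± 0.223 (suboptimal, n = 5). Because FPKM divides by transcript length and by the mapped total, a shift of a few abundant genes or of the mix of short and long transcripts in a library moves the values of all other genes.

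Values were analysed as log2(FPKM + 1) with a pseudocount of 1, as deposited, with no further scaling. Genes with at least 1 FPKM in at least 5 libraries were tested, 13426 in all. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend), 2-sided, without covariates, and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested, with calls at an adjusted p under 0.05. Group, test, filter, gene lists, the rule for named genes and the other settings listed at the end were fixed before the data were examined. The exact permutation test per list, the TPM scale and the first principal component as a covariate were added afterwards. Exact permutation tests over all 462 splits of the 11 libraries, 2-sided, on the difference of mean log2(FPKM + 1), were run per gene and per list. Correlations across libraries used 100000 permutations.

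Fixed gene lists (36) covered proliferation, estrogen, progesterone and sterol pathways, steroid receptors, matrix, vessels, stress, immune response, markers of cell types in the biopsy and signs of RNA quality. The 30 lists with at least 5 tested genes were tested with limma's camera at the preset correlation of 0.01, adjusted over the 30 lists, and beside it with camera at an estimated correlation and with fry. Fry asks whether a list's genes move, on balance, in one direction and does not compare the list with other genes. Named genes were ESR1, PGR, MKI67, ESR2, GREB1, IGF1 and TOP2A in every case; in each direction the 12 genes with the smallest p among called genes with a log2 difference of at least 1, filled up with the next smallest p where fewer qualified, which applied to all of them here; and the 3 genes of each primary list and the 2 of each other described list with the smallest p. Clone names, small RNAs and symbols starting with LOC were left out of these. Some genes that this rule takes in are not reported here. HBB, KRT13, MAL, CNFN and KRT5 were named outside this rule after their values were seen.

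The test was checked on simulated data with 13426 genes, of which 200 were changed by a log2 difference of 1 or 2 (100 each). With independent noise it recovered 69 and 97 of each 100, with 8 false calls, and with the residuals of the real libraries 72 and 97, with 0 false calls. These other settings were pseudocounts of 0.1 and 0.01, no filter, a mean FPKM of at least 5, median-of-ratios and quantile scaling, library quality weights, no trend, robust empirical Bayes, the mean level of the epithelial or the stromal list as a covariate, an adjusted p under 0.1, a floor of 1 on the log2 difference, exact permutation per gene, other set tests and leaving out each library in turn.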

Results

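RNA sequencing measured gene expression in whole endometrium from 11 women who had taken clomiphene citrate, an estrogen receptor modulator used to induce ovulation, at 100 mg on cycle days 3 to 7. Biopsies were taken in the late proliferative phase, on cycle days 12 to 15, when a dominant follicle of at least 19 mm was present. The libraries fell into 2 groups by the thickness of the lining on ultrasound: 6 came from women with an optimal lining of at least 8 mm and 5 from women with a suboptimal lining below 6 mm. Each library is a separate woman, so p-values of single genes and of permutations over libraries measure the spread between women, and nothing pairs the groups. Camera p-values at the preset correlation compare a list's genes with other genes and take little account of that spread. Values are FPKM (fragments per kilobase of transcript, scaled to the mapped total), which summed to between 292415 and 434314 per library, with a mean ± SD of 366734 ± 48033 in the optimal group (n = 6) and 350156 ± 53231 in the suboptimal group (n = 5). The number of genes at 1 FPKM or more was 13192 ± 298 and 13259 ± 449. The number of reads per library is unknown, and the steps between low values put the deepest library at 1.71 times the depth of the shallowest. Group values are given below as mean ± SD over these 6 and 5 libraries, and log2 differences are suboptimal minus optimal on the log2(FPKM + 1) scale, which understates the change of genes with low values.

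The series title sets the comparison as a question about poor proliferation of the lining after clomiphene and about estrogen action. No gene passed limma's test between the groups. Genes of the extracellular matrix, matrix proteases, stromal fibroblasts and mitosis lay mostly lower in the suboptimal group, and genes of T and natural killer cells mostly higher. These gene lists were called when a small preset correlation between genes was assumed, and none was called when the correlation was estimated from the data. The mean log2 difference of the mitosis genes, -0.24, shrank to -0.05 without suboptimal replicate 4. With library quality weights the mitosis list turned to higher and the T and natural killer cell list to lower. The estrogen receptor gene ESR1, the progesterone receptor gene PGR and the listed estrogen-induced genes did not separate the groups.

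Of 13426 genes tested, 0 were called higher and 0 lower by limma at an adjusted p under 0.05, and the smallest adjusted p was 0.995. At an unadjusted p under 0.05 there were 107 genes higher and 169 lower, against an average of 671 in both directions that chance alone gives. Genes vary together, so this count differs widely between groupings, and its median over other splits drawn at random was 181. A count under 671 therefore does not mean that the groups differ less than chance groups do. With the first principal component as a covariate the count was 683. The exact permutation test of each gene over the 462 possible splits called 0 genes, with 303 at an unadjusted p under 0.05. Its smallest possible p is 0.00216, which 8 genes reached. Any call over 13426 genes would need far more genes at that floor, so its 0 calls are no separate support. The groups did not overlap at 17 genes, 10 higher and 7 lower, where chance gives 58 on average (0.433% of genes). The count in both directions was 670 without suboptimal replicate 1, 163 without suboptimal replicate 4, 175 without optimal replicate 3 and 179 without optimal replicate 4, with 0 genes called each time. Most lay lower with all libraries, but most of the 670 without suboptimal replicate 1 lay higher, and with library quality weights 3502 lay higher and 1534 lower, so the balance of the directions turned. The number higher was 70 without optimal replicate 5 and the number lower 270 without optimal replicate 1. On simulated data with these group sizes and 13426 genes, of which 200 were changed, the same test recovered 69 of 100 genes changed by 1 on the log2 scale and 97 of 100 changed by 2. The adjusted threshold is easier to pass when many genes change, so these rates need not hold where few do. In the real data COL12A1, with a log2 difference of -0.97, had an adjusted p of 0.995 by limma.

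ESR1 was at 26.6 ± 7.47 FPKM in the optimal group and 34.9 ± 17.8 in the suboptimal group, a log2 difference of 0.30 ± 0.27 (SE; exact permutation p = 0.366). The suboptimal mean rested on replicate 4 at 64.8 FPKM, and the log2 difference was 0.05 without it and 0.45 without suboptimal replicate 1. PGR, a target of estrogen receptor signalling, was at 50.7 ± 13.5 and 56.2 ± 18.9 FPKM, and its log2 difference of 0.12 ± 0.23 became -0.02 without suboptimal replicate 4. GREB1, an estrogen-induced cofactor of the receptor, was at 14.9 ± 6.51 and 16.1 ± 6.49 FPKM, and its log2 difference of 0.12 ± 0.30 became -0.07 without suboptimal replicate 4 and -0.02 without optimal replicate 6. IGF1, a growth factor of the estrogen-primed stroma, was at 41.9 ± 14.7 and 50.6 ± 13.7 FPKM (log2 difference 0.29 ± 0.25, exact permutation p = 0.344). ESR2, the gene of the second estrogen receptor, stayed at 0.105 ± 0.0351 and 0.115 ± 0.0278 FPKM, below the filter, and was not tested. The proliferation marker MKI67 was at 9.66 ± 4.26 and 7.73 ± 2.36 FPKM (log2 difference -0.23 ± 0.28, exact permutation p = 0.468), and TOP2A, the topoisomerase of dividing cells, at 20.4 ± 9.14 and 17 ± 6.41 FPKM (-0.22 ± 0.31, exact permutation p = 0.554). Leaving out 1 library moved the log2 difference of MKI67 between -0.41 (without optimal replicate 4) and -0.09 (without optimal replicate 1), that of TOP2A between -0.38 and -0.07 (without the same libraries), and that of IGF1 between 0.16 (without optimal replicate 5) and 0.46 (without suboptimal replicate 2). With library quality weights the differences of MKI67 and TOP2A turned to 0.26 and 0.33. The tested genes among these had an adjusted p of 0.995, and the 95% interval for ESR1 ran from -0.28 to 0.89.

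**Figure D1:**
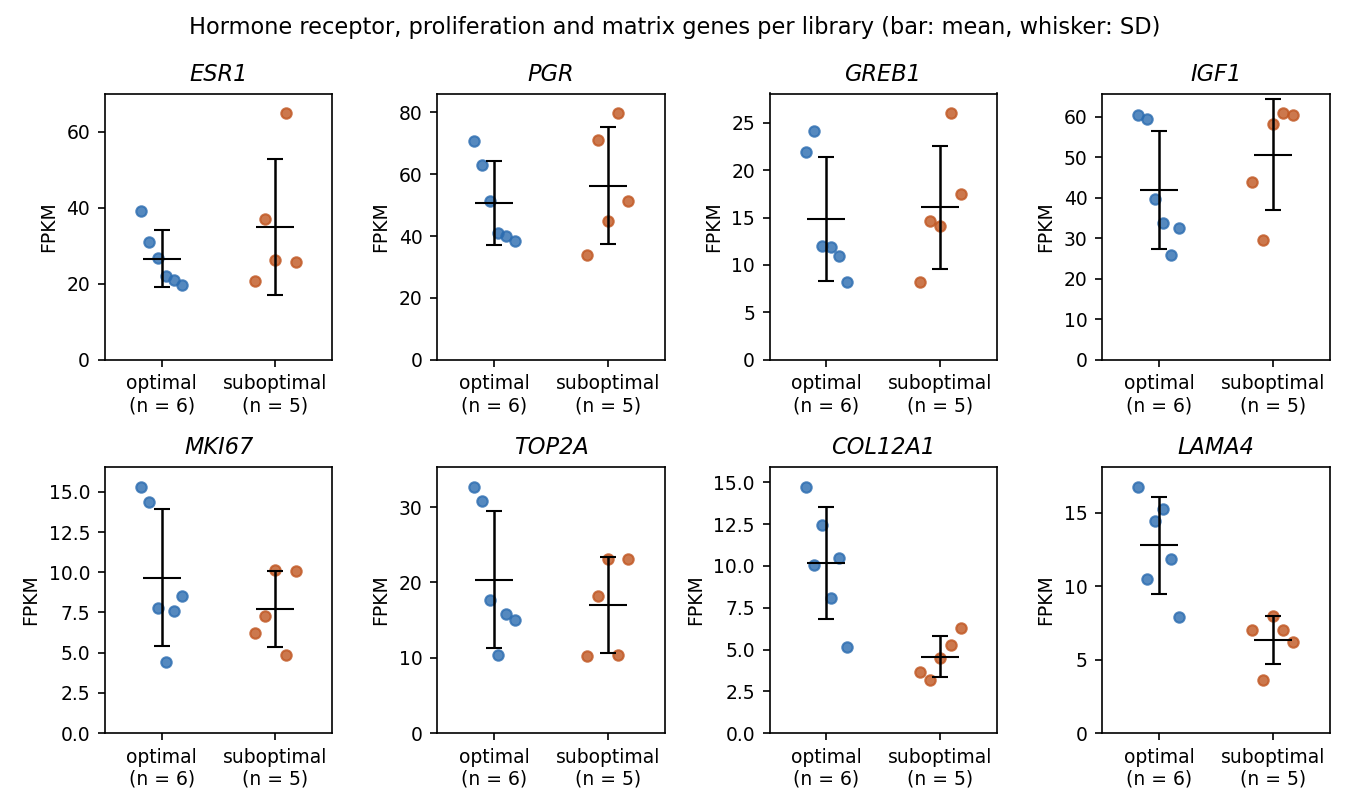
FPKM of ESR1, PGR, GREB1, IGF1, MKI67, TOP2A, COL12A1 and LAMA4 on linear axes in the 6 optimal (blue) and 5 suboptimal (orange) libraries, with points for libraries, a bar at the mean and whiskers of 1 SD. The groups overlap for every gene shown. LAMA4 averages 12.8 in the optimal and 6.34 in the suboptimal group, with a lowest optimal value of 7.89 and a highest suboptimal value of 7.94. No gene passed the test over all genes.

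The genes with the smallest p did not pass the test over all genes, each with an adjusted p of 0.995 by limma. Among those lower in the suboptimal group, COL12A1, a fibril-associated collagen, was at 10.2 ± 3.34 FPKM in the optimal and 4.58 ± 1.23 in the suboptimal group (log2 difference -0.97 ± 0.23, exact permutation p = 0.0108). LAMA4, a laminin chain of vascular basement membranes, was at 12.8 ± 3.31 and 6.34 ± 1.66 FPKM (-0.91 ± 0.21, exact permutation p = 0.00649). HHIP, which binds and restrains hedgehog ligands, was at 4.09 ± 1.18 and 1.76 ± 0.849 FPKM (-0.91 ± 0.21, exact permutation p = 0.00649). Its antisense transcript HHIP-AS1 was at 5.17 ± 0.818 and 3.41 ± 0.840 FPKM, and the use of strand in quantification is not given in the sources used here, so reads of this pair are not surely separated. ITIH3, a chain of a hyaluronan-binding serum protein, had the smallest p of these genes, at 1.66 ± 0.510 and 0.483 ± 0.326 FPKM (-0.84 ± 0.17, exact permutation p = 0.00433). The complement inhibitor CD59 was at 19.4 ± 2.50 and 14.1 ± 1.41 FPKM, and the endocytic adaptor DAB2 at 19.2 ± 2.65 and 13.7 ± 2.55. The remaining genes on this side were CCDC74B, which has the close paralog CCDC74A and is uncertain for that reason, NTPCR, the vascular amine oxidase AOC3, ITM2C and ETNPPL, with log2 differences of -0.46, -0.65, -0.62, -0.53 and -0.53. All 5 suboptimal libraries lay below the optimal median at each of the 12 genes, which their selection by smallest p in this direction makes likely and which is no separate support.

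On the other side, CCDC198 was at 1.04 ± 0.563 FPKM in the optimal and 2.77 ± 0.881 in the suboptimal group (log2 difference 0.90 ± 0.22, exact permutation p = 0.0130). SMPD3, a neutral sphingomyelinase, was at 6.64 ± 1.76 and 13.8 ± 5.19 FPKM (0.89 ± 0.24, exact permutation p = 0.0108). IER3, an immediate early gene that restrains apoptosis, was at 11 ± 3.29 and 18.1 ± 2.47 FPKM (0.71 ± 0.18, exact permutation p = 0.0108). ADAMTSL5, a secreted matrix glycoprotein, was at 4.34 ± 0.613 and 6.38 ± 0.488 FPKM, and MANEAL at 11.7 ± 1.53 and 17.1 ± 2.49, both with the smallest exact permutation p the design allows, 0.00216. RPS6KL1, the calpain CAPN12, the GTPase-activating protein gene ARHGAP26 and the mitochondrial kinase anchor AKAP1 had log2 differences of 0.60, 0.85, 0.71 and 0.63. The decoy receptor TNFRSF6B, whose gene overlaps RTEL1 and is uncertain for that reason, the secreted proteoglycan TSKU and the metalloprotease ADAM8 had log2 differences of 0.44, 0.39 and 0.30. All 5 suboptimal libraries lay above the optimal median at each of the 12 genes, which were likewise selected by smallest p, and none of these genes passed the test over all genes.

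Proliferation genes were compared with a list of 50 genes of G2 and mitosis. All 50 lay lower in the suboptimal group, with a mean log2 difference of -0.24, and 0 of them passed over all genes or adjusted over the list alone. The list mean was 3.33 ± 0.351 and 3.08 ± 0.513 in log2(FPKM + 1). Camera called the list lower with its preset correlation (adjusted p = 4.44e-10), and the adjusted p was 0.789 with an estimated correlation. TACC3, a spindle protein, was at 35.3 ± 7.31 and 28.2 ± 10.6 FPKM. CDC20, the activator of the anaphase-promoting complex, was at 39.7 ± 8.16 and 31.4 ± 14 FPKM, and BIRC5 (survivin) at 24.4 ± 5.23 and 19.4 ± 9.31. Without suboptimal replicate 4 the mean log2 difference was -0.05 and the adjusted p 0.108, and the mean was -0.37 without optimal replicate 4 and -0.38 without suboptimal replicate 3. Of 49 tested genes of DNA replication, 39 lay lower and 10 higher, 0 passed over all genes or adjusted over the list alone, and the mean log2 difference was -0.08 (camera adjusted p = 0.00844; adjusted p = 0.871 with an estimated correlation). Thymidine kinase TK1 was at 52.1 ± 17.1 and 42.0 ± 19.9 FPKM and the replication clamp partner PCLAF at 17.2 ± 3.62 and 14.3 ± 5.0. The replication list turned to higher without suboptimal replicate 4 (adjusted p = 0.641), and its call ended without suboptimal replicate 2 (0.245) or optimal replicates 1, 2 or 6 (0.365, 0.167 and 0.608). The mean log2 differences in these 4 cases were -0.04, -0.04, -0.05 and -0.03. The mean was -0.17 without optimal replicate 4 or suboptimal replicate 3, and -0.13 without suboptimal replicate 5. On the TPM scale, chosen after seeing the data, the median log2 difference of all genes moved from 0.02 to 0.08, the replication mean was -0.02 and its call held (adjusted p = 0.0125). With library quality weights both lists turned to higher, with adjusted p of 0.404 for mitosis and 0.0249 for replication.

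Estrogen action was compared with 48 tested genes that estradiol induces in breast cancer cells and 26 known as estradiol-responsive or proliferative-phase genes of the endometrium. In the breast cancer list 28 genes lay higher and 20 lower (mean log2 difference 0.03, camera adjusted p = 0.385), and 0 passed over all genes or adjusted over the list alone. Leaving out 1 library moved this mean between -0.01 (without suboptimal replicate 4, with a camera direction still higher) and 0.08 (without suboptimal replicate 1), and it was 0.09 on the TPM scale. HSPB8, a small heat shock protein, was at 27.5 ± 10.2 and 41.4 ± 9.35 FPKM, FKBP4, a cochaperone of steroid receptors, at 58.9 ± 6.27 and 71.3 ± 7.84, and the transcription factor MYB at 1.82 ± 0.526 and 2.74 ± 0.782. All 5 suboptimal libraries lay above the optimal median for each of these 3 genes, which were selected for the smallest p of the list. The endometrial list had 15 genes higher and 11 lower, with a median log2 difference of 0.04, a mean of -0.03 and a camera direction of higher (adjusted p = 0.957), so its median and its test differed in sign from its mean; 0 genes passed over all genes or adjusted over the list alone. Its mean was 0.04 without suboptimal replicate 1 (median 0.18) and -0.10 without suboptimal replicate 5, and its camera direction was lower without optimal replicates 3 or 5 or suboptimal replicates 4 or 5. After quantile normalization its mean was 0.0056, and on the TPM scale 0.03 with a camera direction of lower (adjusted p = 0.796). In it NDP, the Wnt-pathway ligand norrin, was at 8.12 ± 2.95 and 4.47 ± 1.25 FPKM (log2 difference -0.72 ± 0.21, exact permutation p = 0.00866). The epithelial mucin MUC1 was at 88.5 ± 29 and 131 ± 44.5 FPKM, and the matrix protein gene CILP at 4.36 ± 1.61 and 7.04 ± 3.02.

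Of 36 tested progesterone-regulated and secretory-phase genes, 16 lay higher and 20 lower (mean log2 difference -0.07, camera adjusted p = 0.333). The estradiol-inactivating enzyme HSD17B2 was at 1.77 ± 1.43 and 0.556 ± 0.441 FPKM, the secretoglobin SCGB1D2 at 81.1 ± 56.8 and 32.3 ± 20.4, and the ectonucleotidase ENPP3 at 8.17 ± 5.53 and 4.22 ± 3.52. The progesterone list was called lower without optimal replicate 1 (mean -0.16, adjusted p = 0.0483) at the preset correlation; with all libraries its adjusted p was 0.811 with an estimated correlation. Its mean was -0.02 without optimal replicates 3, 4 or 6 or on the TPM scale, and -0.04 without suboptimal replicates 4 or 5. Of 27 genes of cholesterol synthesis and uptake, a pathway that compounds related to clomiphene inhibit, 17 lay higher and 10 lower (mean log2 difference 0.07, camera adjusted p = 0.0997). TMEM97, a sterol-regulated membrane protein, was at 13.8 ± 2.35 and 15.8 ± 1.21 FPKM and squalene epoxidase SQLE at 13 ± 4.0 and 15.6 ± 3.26. The sterol list was called higher without optimal replicates 1, 5 or 6 (adjusted p = 0.0316, 0.00366 and 0.0169) or suboptimal replicates 2 or 5 (0.0281 and 0.0163), all at the preset correlation. With all libraries its adjusted p was 0.811 with an estimated correlation. Its mean was 0.03 without optimal replicate 4 and 0.14 on the TPM scale. Of 25 steroid receptors and cofactors, 17 lay higher and 8 lower (mean log2 difference 0.07, camera adjusted p = 0.252), and the list turned to lower without suboptimal replicate 4 (mean -0.02, adjusted p = 0.641). The receptor mean was 0.17 without suboptimal replicate 1, 0.14 and 0.12 without optimal replicates 1 and 2, 0.05 and 0.02 without optimal replicates 5 and 6, and 0.15 on the TPM scale. The membrane estrogen receptor GPER1 was at 7.82 ± 1.99 and 5.37 ± 1.64 FPKM, and GATA2, a partner of the progesterone receptor, at 36.8 ± 8.02 and 48.0 ± 13.8. In these 3 lists 0 genes passed over all genes or adjusted over the list alone.

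Matrix genes made up the list with the smallest camera p. Of 41 tested, 39 lay lower and 2 higher, with a mean log2 difference of -0.30; 0 passed over all genes and 2, COL12A1 and LAMA4, adjusted over the list alone. Camera called the list lower (adjusted p = 3.91e-12), and the adjusted p was 0.512 with an estimated correlation. All 20 tested matrix proteases and inhibitors lay lower, with a mean log2 difference of -0.30, and 0 passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 8.17e-08 for them, and the adjusted p was 0.432 with an estimated correlation. The exact permutation test of their mean level, 4.72 ± 0.195 against 4.41 ± 0.193, gave p = 0.0368 before and 0.881 after adjustment over the lists. This test has too few possible splits to bring a list that stands alone under the adjusted threshold. The membrane protease MMP14 was at 186 ± 34.9 and 142 ± 42.7 FPKM, and the urokinase gene PLAU at 10.9 ± 2.43 and 8.04 ± 2.41. Of 25 markers of stromal fibroblasts, 8 of which are also in the matrix list, 20 lay lower and 5 higher (mean log2 difference -0.27); 0 passed over all genes and 1, LAMA4, adjusted over the list alone. Camera called the stromal list lower (adjusted p = 7.52e-07), and the adjusted p was 0.512 with an estimated correlation. The fibroblast surface marker THY1 was at 143 ± 32.9 and 86.4 ± 44.7 FPKM (log2 difference -0.87 ± 0.34, exact permutation p = 0.0346). The mean log2 differences of the stromal and matrix lists were -0.12 and -0.20 without suboptimal replicate 2, and the calls held (adjusted p = 0.0281 and 3.52e-06). With the stromal level as a covariate the matrix list was no longer called (adjusted p = 0.0703).

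Smooth muscle, pericyte and endothelial markers also lay mostly lower, and 0 of their genes passed over all genes or adjusted over the list alone. Of 14 smooth muscle genes, 12 were lower and 2 higher (mean log2 difference -0.35, camera adjusted p = 3.39e-06; adjusted p = 0.512 with an estimated correlation). Smooth muscle actin ACTA2 was at 58.8 ± 26.4 and 35.8 ± 13.0 FPKM and TAGLN (transgelin) at 45.0 ± 21.8 and 23.8 ± 9.65. Without optimal replicate 4 the mean log2 difference of the smooth muscle list was -0.18, and the call held at the preset correlation (adjusted p = 4.39e-04). All 11 pericyte genes were lower (mean -0.20, camera adjusted p = 9.66e-04; adjusted p = 0.512 with an estimated correlation), among them NDUFA4L2 at 5.41 ± 2.51 and 3.31 ± 1.02 FPKM and CD248 (endosialin) at 116 ± 13.6 and 96.0 ± 25.8. Of 20 endothelial genes, 16 were lower and 4 higher (mean -0.17, camera adjusted p = 2.75e-04; adjusted p = 0.789 with an estimated correlation). VWF (von Willebrand factor) was at 21.8 ± 4.49 and 16.3 ± 6.39 FPKM and the receptor ACVRL1 at 6.16 ± 1.14 and 4.78 ± 1.65. The pericyte and endothelial calls ended without suboptimal replicate 2, both with an adjusted p of 0.150 and with means of -0.10 and -0.08, and the endothelial mean was -0.30 without suboptimal replicate 5. Of 25 angiogenic factors and receptors, 14 were lower and 11 higher (mean -0.08, camera adjusted p = 0.0359; adjusted p = 0.811 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. The vasodilator adrenomedullin, ADM, was at 1.84 ± 0.792 and 0.918 ± 0.212 FPKM and the matrix protein gene THBS2 at 8.32 ± 4.01 and 3.87 ± 0.883. The angiogenic call ended without optimal replicates 1, 2 or 4 (adjusted p = 0.119, 0.215 and 0.0936) or suboptimal replicates 1 or 2 (0.336 and 0.550), with means of -0.06, -0.05, -0.06, -0.01 and -0.02 in that order. Its mean was -0.14 without optimal replicate 6 and -0.16 without suboptimal replicate 5, and on the TPM scale it was -0.03 with the call held (adjusted p = 0.0212). With the stromal level as a covariate the endothelial and angiogenic lists turned to higher (adjusted p = 0.989 and 0.654), and the pericyte list was no longer called (0.654). With library quality weights the endothelial and angiogenic lists also turned to higher (0.696 and 0.908) and the pericyte call ended (0.399). The log2 difference of VWF was then 0.0037.

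T and natural killer cell genes lay higher in the suboptimal group. Of 16 tested, 15 were higher and 1 lower (mean log2 difference 0.25, camera adjusted p = 3.39e-06; adjusted p = 0.512 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The chemokine CCL5 was at 10.6 ± 1.68 and 14.6 ± 3.53 FPKM, and the chemokine XCL2, whose reads are hard to separate from its near-identical paralog XCL1, at 1.45 ± 0.694 and 2.52 ± 0.753. Without suboptimal replicate 1 the mean log2 difference was 0.20 and the adjusted p 0.0753, and without suboptimal replicate 4 the mean log2 difference was 0.15 (adjusted p = 9.78e-05). With library quality weights the T and natural killer cell list turned to lower (camera adjusted p = 0.415). Of 22 ciliated cell genes, 20 were higher and 2 lower (mean 0.22, camera adjusted p = 0.00718; adjusted p = 0.811 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. CCDC113 was at 1.85 ± 0.289 and 2.58 ± 0.938 FPKM and ARMC3 at 1.10 ± 0.340 and 1.75 ± 1.09. Without suboptimal replicate 2 the ciliated list turned to lower (mean -0.07, adjusted p = 0.60), and its call ended without optimal replicate 1 (0.524, mean 0.08) or suboptimal replicate 5 (0.378, mean 0.05). Its mean was 0.40 without suboptimal replicate 1 and 0.42 without suboptimal replicate 4. Of 28 interferon-induced genes, 22 were lower and 6 higher (mean -0.16, camera adjusted p = 8.09e-05; adjusted p = 0.521 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. The antiviral genes OAS1 and IFIT1 were at 3.55 ± 1.37 and 2.21 ± 0.498 FPKM and at 2.01 ± 0.738 and 1.27 ± 0.317.

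**Figure D2:**
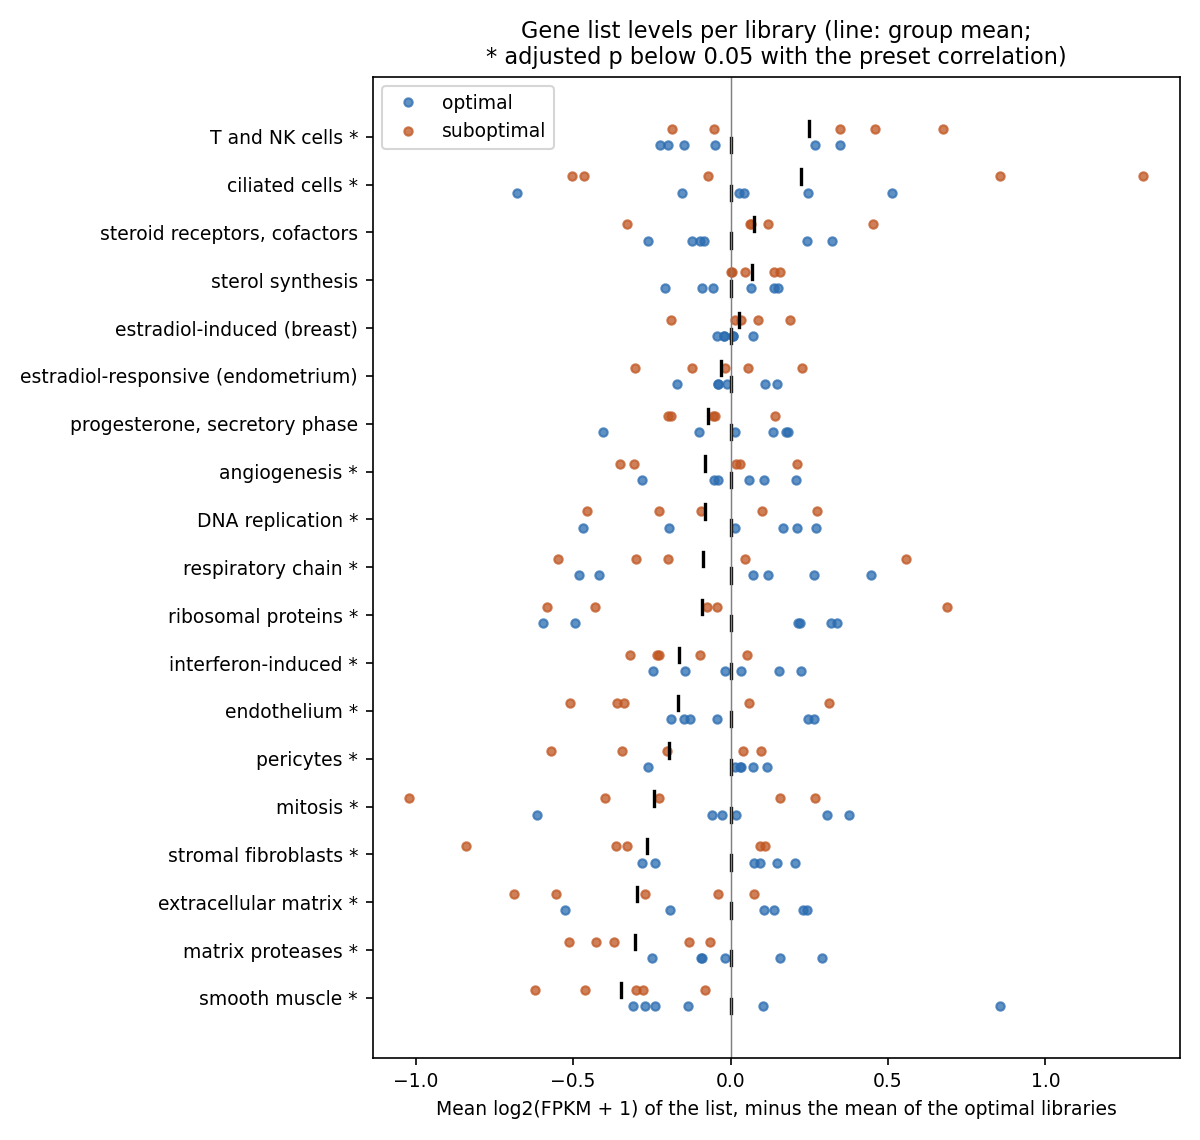
Mean log2(FPKM + 1) of each gene list per library, minus the mean of the 6 optimal libraries, for the 5 primary lists without a call and the 14 called lists (asterisk), with points for libraries (blue optimal, orange suboptimal) and a line at each group's mean. The groups overlap in every list shown; all 20 matrix proteases lie lower on average with a mean difference of -0.30, and no list is called with an estimated correlation.

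Ribosomal protein and respiratory chain genes lay lower by small amounts, and the sign of both lists depended on the settings. Of 80 ribosomal protein genes, 74 were lower and 6 higher (mean log2 difference -0.09, camera adjusted p = 0.0223; adjusted p = 0.893 with an estimated correlation), and after quantile normalization the list turned to higher (adjusted p = 0.120). RPS27L was at 38.1 ± 10.04 and 30.6 ± 4.91 FPKM and RPL36A at 2.31 ± 0.573 and 3.00 ± 1.06; many genes of this family have processed pseudogenes, so their values are uncertain. Of 60 respiratory chain genes, 52 were lower and 8 higher (mean -0.09, camera adjusted p = 0.0250; adjusted p = 0.871 with an estimated correlation), and after quantile normalization the mean was still lower, at -0.02 (adjusted p = 0.613). NDUFS5 was at 306 ± 106 and 254 ± 167 FPKM and NDUFA5 at 7.50 ± 0.387 and 8.22 ± 0.422. In both lists 0 genes passed over all genes or adjusted over the list alone. With median-of-ratios scaling the adjusted p of both lists was 0.0512 while their mean log2 differences were larger, at -0.11 for ribosomal proteins and -0.10 for the respiratory chain. On the TPM scale both means were -0.02 and the calls held (adjusted p = 0.00864 and 0.0235). With the first principal component as a covariate, chosen after seeing the data, camera called both lists higher at the preset correlation. The means were then 0.08 for ribosomal proteins (adjusted p = 6.45e-09) and 0.06 for the respiratory chain (3.78e-07). Both lists turned to higher without suboptimal replicate 4 (0.305 for ribosomal proteins and 0.260 for the respiratory chain). Without suboptimal replicate 5 the camera direction of the ribosomal list was higher (0.809) at a mean log2 difference of -0.0037, and its call ended without optimal replicates 3, 4, 5 or 6 (0.301, 0.368, 0.451 and 0.827) or suboptimal replicate 3 (0.158). The ribosomal mean was -0.05, -0.05, -0.03 and -0.02 in the first 4 of these cases and stayed at -0.09 without suboptimal replicate 3. The respiratory list also turned to higher without optimal replicate 6 (0.712), and its call ended without optimal replicates 3, 4 or 5 (0.157, 0.0887 and 0.419) or suboptimal replicates 2 or 5 (0.227 and 0.798), with means of -0.06, -0.07, -0.03, -0.06 and -0.03 in that order. Leaving out suboptimal replicate 1, or optimal replicate 1 or 2, made both differences larger, with means of -0.28, -0.21 and -0.19 for ribosomal proteins and -0.25, -0.18 and -0.17 for the respiratory chain.

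In all, camera with its preset correlation called 14 of 30 lists, 2 higher and 12 lower. With an estimated correlation it called 0, with adjusted p between 0.432 and 0.893 for the 14, and fry also called 0. The exact permutation test of the list mean called 0 too. Its possible splits are too few to call a list over 30 lists unless other lists have p-values about as small. Its 0 calls are therefore no separate evidence against a difference of any list. Before adjustment, 1 list had an exact permutation p under 0.05. The mean correlation among a called list's genes ran from 0.176 for matrix proteases to 0.871 for ribosomal proteins, against the preset 0.01. The number called higher was 4 without optimal replicate 6 and 1 without suboptimal replicate 1, and the number called lower was 7 without suboptimal replicate 2.

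Lists with no call by camera covered the Wnt pathway (adjusted p = 0.626), growth factors (0.660), hypoxia-induced genes (0.181), p53 targets (0.333), the unfolded protein response (0.203), inflammatory cytokines (0.660), immediate early and heat shock genes (0.295), replication-dependent histones (0.816), epithelial cells (0.626), luminal epithelium (0.957) and macrophages (0.134). At the preset correlation, leaving out 1 library gave a call lower for macrophages without optimal replicate 1 (mean log2 difference -0.27 against -0.08 with all libraries, adjusted p = 5.57e-06) or suboptimal replicate 3 (-0.16, 0.0203), higher for histones without suboptimal replicate 4 (0.19 against 0.02, 3.59e-04) and higher for epithelial cells without optimal replicate 6 (0.08 against 0.0098, 0.0169). With all libraries the adjusted p of these 3 lists was 0.871, 0.950 and 0.929 with an estimated correlation. Their signs also turned: the mean was 0.07 for macrophages without optimal replicate 4. Without suboptimal replicate 2 it was -0.07 for histones and -0.08 for epithelial cells, with no call in these cases. The Wnt list had a positive median and mean log2 difference (0.02 and 0.0027) and a camera direction of lower. Its mean was 0.10 without suboptimal replicate 1, with a camera direction of higher, -0.06 without optimal replicate 6 and -0.05 without suboptimal replicate 4. Among these lists 0 genes passed over all genes, and 1, IER3 in the immediate early list, passed adjusted over the list alone. A further 6 lists had fewer than 5 tested genes and were not tested as lists: mitochondrial RNA (0 genes), B and plasma cells (4), neutrophils (3), mast cells (2), red blood cells (2) and squamous cells of the cervix (4). Hemoglobin beta, HBB, was at 42.3 ± 45.3 and 125 ± 160 FPKM, with suboptimal replicate 2 at 404. The squamous keratin gene KRT13 was at 4.25 ± 1.80 and 9.64 ± 5.84 FPKM (log2 difference 0.94, limma adjusted p = 0.995), and the other squamous genes went both ways, with log2 differences of 0.50 for MAL, -0.19 for CNFN and -0.52 for KRT5.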

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

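In this part the use of the estimated correlation, itself a setting fixed beforehand, as a test of where the list calls come from, the count of splits past the adjusted threshold and the tests of the first axis against the groups and against depth were chosen after the result was seen. In groups of 5 or 6 libraries, the highest or lowest library lay far from the others for 7 of 182 combinations of group and gene or list examined, and chance gives about 5% of them, or 1 in 20 groups. SMPD3 was at 10.2 FPKM in optimal replicate 2, where the other optimal libraries lay between 5.28 and 6.24. TSKU was at 60.6 FPKM in suboptimal replicate 4, against 42.5 to 46.4 in the others of its group. TMEM97 was at 9.53 FPKM in optimal replicate 4, against 13.6 to 16.5. ARMC3 was at 1.76 FPKM in optimal replicate 2, against 0.764 to 1.06. ACTA2 was at 58.7 FPKM in suboptimal replicate 3, against 28.3 to 32.9. The mean log2 level of the smooth muscle list was 3.90 in optimal replicate 4, against 2.74 to 3.15 in the other optimal libraries. The mean log2 level of the pericyte list was 2.80 in optimal replicate 6, against 3.08 to 3.18.

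The calls of gene lists with the preset correlation were set against chance and against correlation between the genes of a list. Of 100 splits of the 11 libraries into groups of 6 and 5, the real one included, 37 called as many lists as the real 14, the highest of the other splits called 21 and their median was 12, so chance could not be excluded. Of the 14 lists, 0 kept an adjusted p under 0.05 with an estimated correlation, which fits a correlation between their genes as the source of the small p-values. The mitosis list was called in 76 of the 100 splits and had a p as small as the real one in 42; the matrix list had a p as small in 11 and the matrix proteases in 5. Differences between the women that have nothing to do with lining thickness may therefore account for most of these calls. The other called lists were not set against the splits singly. A real difference of any of these lists, the matrix proteases included, is neither shown nor excluded.

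For single genes, 37 of 100 splits gave as many genes at an unadjusted p under 0.05 as the real split, with its 107 higher and 169 lower. The median of the other splits was 181 and the highest 3681, which points to a structure of the samples other than the study's groups. Chance could not be excluded for the real count. At an adjusted p under 0.05 the real count is 0, which all 100 splits reach by construction, so that count decides nothing; 3 splits called any gene, and the highest other count was 3.

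The first axis of a principal component analysis held 57.4% of the variance among libraries and the second 10.6%. The groups accounted for a share of 0.041 of the spread on the first axis (exact permutation p = 0.539), which argues against lining thickness as its source. Depth, as far as the low values measure it, is argued against too. The reason is that 2 libraries with relative depths of 0.994 and 1.01 lay 0.915 of the axis range apart. Across 12984 genes, which are not independent replicates, without ribosomal protein and respiratory chain genes, the axis loading went with transcript length (Spearman rho -0.374) and GC content (rho 0.456). A technical difference in library preparation or RNA quality that acts through length and GC content may contribute to the axis, and the design gives no biological group that could be tested against it apart from lining thickness. Variation of RNA content or cell makeup between women stays open and untested.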

How the results depend on the processing

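The TPM scale, the first principal component as a covariate and the exact permutation of list means were added after seeing the data. Limma called 0 genes under each alternative, leave-one-out included. Its smallest adjusted p was 0.0675 with library quality weights, 0.151 with the first principal component and 0.191 with the epithelial covariate, against 0.995 in the main fit. The threshold of 0.1 was applied to the main fit only. Named genes kept their direction and their side of the threshold in 1618 of 1627 alternative values, with 9 reversed over 6 genes. None was called in the main fit, so their side of the threshold says little. Causes were not tested, except that leaving out a library leaves fewer samples. With library quality weights, which ran from 0.225 to 4.93 (optimal replicate 3), log2 differences turned to 0.26 for MKI67, 0.33 for TOP2A, 0.044 for PCLAF and 0.0037 for VWF; adjusted p of lists that turned were 0.404 for mitosis, 0.0249 for DNA replication, 0.808 for the breast cancer estrogen list, 0.908 for angiogenesis, 0.696 for endothelium and 0.415 for T and natural killer cells; the progesterone list was called (0.00757), lists called higher were 1 and lower 7, and genes at an unadjusted p under 0.05 numbered 5036. With the stromal level as a covariate, the breast cancer estrogen (0.969), angiogenesis (0.654) and endothelium (0.989) lists turned, DNA replication was not called (0.325), and lists called higher were 1 and lower 7. With the first principal component as a covariate, PGR was at -0.030 and GREB1 at -0.088, the endometrial estrogen (0.725), progesterone (0.960), receptor (0.863), respiratory chain (3.78e-07) and ribosomal protein (6.45e-09) lists turned, sterol synthesis was called (0.00833) and 5 lists were called higher. The endometrial estrogen list, whose direction is uncertain, also turned without trend (0.989), on the TPM scale (0.796) and by exact permutation (0.892). Ribosomal proteins turned with quantile normalization (0.120), sterol synthesis was called at a mean FPKM of at least 5 (0.024), and 4 lists were called higher with no filter. With an estimated correlation, fry or exact permutation, 0 lists were called higher and 0 lower. Adjusted p in that order were 0.789, 0.915 and 0.892 for mitosis and 0.871, 0.915 and 0.892 for DNA replication. Exact permutation has too few possible splits to call a list that stands alone, so its 0 calls are no separate support. Further calls ended with library quality weights for stroma (0.231), pericytes (0.399) and ciliated cells (0.153), with the stromal covariate for matrix (0.0703), pericytes (0.654) and ciliated cells (0.530), with no filter for angiogenesis (0.0958), the respiratory chain (0.0678) and ribosomal proteins (0.0737), and at a mean FPKM of at least 5 for ciliated cells (0.414), the respiratory chain (0.124) and ribosomal proteins (0.0674). Leaving out each library gave ranges of -0.022 to 0.28 for PGR, -0.067 to 0.32 for GREB1, 1 to 4 lists higher and 7 to 12 lower, and adjusted p of 3.66e-27 to 0.108 for mitosis, 6.17e-11 to 0.641 for DNA replication, 0.641 to 0.931 for the endometrial estrogen list, 0.0483 to 0.922 for progesterone, 0.00366 to 0.775 for sterol synthesis, 0.0609 to 0.712 for receptors, 1.84e-10 to 0.798 for the respiratory chain, 1.09e-12 to 0.827 for ribosomal proteins and 2.12e-10 to 0.60 for ciliated cells. Unadjusted p under 0.05 held for 53 to 3502 genes higher and 100 to 1534 lower over all alternatives. Scaling moved the median log2 difference of all genes from 0.02 to 0.08 at most (TPM scale). No symbol was repeated, so summing by symbol could not be varied; robust empirical Bayes does not enter camera and was not run for lists, and the stromal and epithelial lists were not tested under their own covariate. No paired analysis was possible because replicate numbers only name the libraries. Depth is known only in relative terms, so its limit on low genes could not be computed.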

Other observations

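The tests of relations with the first axis in this part were chosen after the axis was seen. The axis was computed from the same gene values, those of ESR1, PGR and the listed genes among them. Its sign was set to follow the sum of FPKM. Relations of the axis with these genes, lists and the sum therefore describe the axis, and their p-values are no independent support. ESR1 and PGR varied together across the 11 libraries (Pearson r = 0.925, permutation p = 1e-05, the smallest these permutations can give; Spearman rho = 0.955, permutation p = 2e-05; adjusted 3.25e-05 and 6.5e-05 over 13 relations), with r = 0.962 without the 2 libraries farthest from the median. Within the optimal group r was 0.989 over 6 libraries, and no value was computed over the 5 suboptimal libraries. Both went against the first axis, with r = -0.874 for ESR1 (rho = -0.909, permutation p = 6e-05 and 1.6e-04, adjusted 1.3e-04 and 3.47e-04) and r = -0.933 for PGR (rho = -0.936, permutation p = 5e-05 for each, adjusted 1.3e-04 for each). The hypothesis that the first axis alone links the 2 receptor genes was tested by their partial correlation given the axis, which was 0.625 (permutation p = 0.0403). That value does not decide whether the axis is the whole cause. No other gene pairs were compared in this way, and only the first axis was taken into account. A shared regulation of the 2 genes stays open, as a hypothesis found on these same data.

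The first axis went with the sum of FPKM (r = 0.996, rho = 1, permutation p = 1e-05 for each, adjusted 3.25e-05 and 4.33e-05), with the ribosomal protein list (r = 0.971, rho = 0.973) and with the respiratory chain list (r = 0.985, rho = 0.991), the last 2 with the same p-values as the sum. The axis was built from these same values, so the p-values are no separate support. Relations with relative depth (r = -0.0131, rho = -0.00909, permutation p = 0.968 and 0.989), MKI67 (r = -0.372, rho = -0.345, permutation p = 0.258 and 0.298) and the mitosis list (r = -0.0511, rho = -0.273, permutation p = 0.880 and 0.418) did not pass the test over all libraries. Without the 2 libraries farthest from the median these r were -0.117, 0.0544 and -0.697, and within the 6 optimal libraries 0.351, -0.807 and -0.671, so a relation of the axis with proliferation genes is not excluded. Between the lowest and highest axis score, the fitted log2 change had a median of 0.31 in the quartile of genes with the highest GC content and -0.58 in the quartile with the lowest, and by transcript length it was 0.08, 0.13, -0.25 and -0.63 from the shortest to the longest quartile. The most alike libraries by Spearman correlation across genes were suboptimal replicate 5 and optimal replicate 2 (0.988), and the least alike were suboptimal replicates 4 and 1 (0.886).

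The T and natural killer cell list and the mitosis list varied in opposite directions (Pearson r = -0.677, permutation p = 0.0202, adjusted 0.0375; Spearman rho = -0.482, permutation p = 0.136, adjusted 0.221), and without the 2 libraries farthest from the median r was -0.304, while within the 6 optimal libraries it was -0.585, so the relation over all libraries rests in part on those 2. Stromal and epithelial list levels also varied in opposite directions (r = -0.665, permutation p = 0.0294, adjusted 0.0478; rho = -0.482, permutation p = 0.135, adjusted 0.221; r = -0.692 without the 2 libraries farthest from the median). A smaller share of stromal relative to epithelial cells could lower the stromal and matrix lists in the suboptimal group: the stromal minus epithelial level was 1.17 ± 0.451 in the optimal group (n = 6) and 0.897 ± 0.554 in the suboptimal group (n = 5), a difference of -0.28 with an exact permutation p of 0.400. The sign of this difference follows from the lower stromal list itself (-0.27), since the epithelial list differed by 0.0098, so it is no support for the hypothesis. The difference is within the spread between women, and the hypothesis stays open. ESR1 and the mitosis list (r = -0.337, rho = 0.1, permutation p = 0.307 and 0.776) and the ciliated and epithelial lists (r = 0.462, rho = 0.327, permutation p = 0.154 and 0.332) showed no relation past the test. Without the 2 libraries farthest from the median r was 0.314 and 0.324, and within the 6 optimal libraries 0.648 and 0.260, so the sign for ESR1 and mitosis depended on the libraries included.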
